A study of Mus musculus with 8 samples.

How the data were processed

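RNA from whole skin of mouse embryos at E18.5 (embryonic day) was measured on single-colour Affymetrix oligonucleotide arrays, which carry short probes for each transcript grouped into probe sets. The embryos came from crosses of mice heterozygous for a p63 mutation, and the design names 2 p63 null and 2 wild-type embryos. Each genotype has 2 arrays of the A chip and 2 arrays of the B chip of the same mouse array set, 8 arrays in all. The chips carry different probe sets, so each chip was analysed on its own. The labels number the embryos 1 and 2 within each genotype and chip, and do not state outright that a number stands for the same embryo on both chips. Group membership was taken from the sample titles. The titles number the replicates in both genotypes, but no source ties a null embryo to a wild-type embryo of the same number, so the genotypes were compared without pairing.

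Per the labels' protocols, total RNA was extracted with TriZol, cleaned on RNeasy columns and labelled with biotin. The deposited values are linear-scale intensities per probe set, made with MAS5 per the submitters' processing notes. MAS5 summarises the perfect-match and mismatch probes of each probe set into 1 signal. Its version and its detection calls are not given in the sources used here, so no probe set could be called present or absent. Values at the low end are therefore described only by their level. On each chip the arrays had nearly the same 2% trimmed mean signal, 250.1 to 250.2 on the A chip and 500.1 on the B chip, so the deposited intensities had already been scaled. The A chip held 12488 probe sets and the B chip 12477, with no missing values and 2 values of 0, both on the A chip. The number of arrays limits the precision of every comparison.

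Each array was rescaled to the same 2% trimmed mean. An offset equal to the 20th percentile of the rescaled signals of the chip (12.9 on the A chip, 54.3 on the B chip) was added before taking log2. Log2 fold changes are null minus wild type on this log2(signal + offset) scale, which understates the change of genes with low signal. The 66 control probe sets of each chip were left out, and probe sets were tested when their mean log2 value over the 4 arrays of the chip was above the 40th percentile, which left 7453 on the A chip and 7446 on the B chip. Linear models were fitted with limma (lmFit, then eBayes with an intensity trend in the variance), two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested on that chip, with a threshold of 0.05. Every adjusted p for a gene below comes from this limma fit. Means ± SD are of the deposited signals of the 2 embryos of a genotype. Probe sets from large gene families can bind transcripts of related genes, which concerns the Sprr2, Lce1, keratin, desmoglein and Hspa1 probe sets in particular.

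Probe sets were named through the platform annotation, which can be old. On the A chip 10855 probe sets had 1 symbol, 396 had several and 1237 had none. On the B chip the numbers were 10603, 178 and 1696. Of the probe sets with 1 symbol, 10839 on the A chip and 10572 on the B chip were found by gene identifier in the RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols needed updating. No probe set with several symbols was named. No genome build is given in the sources used here, so no coordinates are printed. Where a gene had several tested probe sets, the one with the highest mean signal stood for it.

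Gene lists for 19 cell types and processes were written from general knowledge before the data were examined, as were the tests, the filter, the offset and the rule for the genes named. The lists cover basal keratinocytes, suprabasal keratinocytes, the cornified envelope, the epidermal lipid barrier, desmosomes and adherens junctions, hair follicles, simple epithelium, proposed p63 targets, dermal fibroblasts and matrix, skeletal muscle, adipocytes, erythroid cells, leukocytes, endothelium, Schwann cells with neurons and melanocytes, cartilage and bone, the cell cycle, immediate early and stress genes, and sex-linked genes. Some lists share members. Of the 25 basal keratinocyte genes 11 are also in another list, and of the 46 proposed p63 targets 15 are. Of the list symbols, Pvrl1 and Mcpt6 were matched through a synonym and Ahsp was not matched. Each list with at least 5 tested genes was compared with the other tested genes by limma's camera with its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of the chip (17 on the A chip, 8 on the B chip). Camera with a correlation estimated from the residuals and limma's fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were run beside it. The members of a list were also adjusted over the list alone.

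The genes named are Trp63, then, among genes with 1 symbol that passed the threshold and whose null arrays both lay on one side of both wild-type arrays, the 8 largest falls and 8 largest rises on the A chip and the 5 largest of each on the B chip, and for each list up to 4 members past the threshold with the largest change, or the 2 with the highest signal where none passed. Other genes are named where the text says so.

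The fits were tested on simulated data with the real levels and spread and 2 arrays per group. The simulated genes varied independently of each other. On the simulated A chip 2% of probe sets changed by 0.5 log2 units were recovered, 50% of those changed by 1, 96% of those changed by 2 and 100% of those changed by 3. On the simulated B chip the shares were 2%, 26%, 88% and 98%. Each share is of 50 probe sets. The simulation changed only 233 of 7453 tested probe sets on the A chip and 202 of 7446 on the B chip. In the real data 44.3% and 29.4% of the tested probe sets were called. The Benjamini-Hochberg cutoff was therefore stricter in the simulation, and these shares do not give the power of the real comparison. Of the 151 calls on the simulated A chip 6 were false, and of the 118 on the simulated B chip 8. A skeletal muscle list of 34 genes was shifted by 1 log2 unit on the simulated A chip. Its camera adjusted p was 7.05e-49 with the preset correlation and 0.0564 with an estimated one, so the latter missed the shift. Camera with the preset correlation called 0 of 16 other lists. On the simulated B chip a shifted basal keratinocyte list of 6 genes had adjusted p-values of 8.51e-13 and 0.134, and 1 of 7 other lists was called. With independent genes these runs favour the preset correlation and cannot show that it is adequate for the real lists. The estimated correlations of the real lists ran from -0.0755 to 0.214 on the A chip and from -0.177 to 0.421 on the B chip.

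The alternatives tried were the values as deposited, quantile normalization, median centring, no offset, a floor in place of the offset, the 40th percentile as offset, no filter, a filter at the 60th percentile, no variance trend, a robust variance fit, the replicate number as a block, leaving out each array in turn, and a 2-fold threshold. For the lists they also included the mean over a gene's probe sets, only probe sets of the plain class, the estimated correlation and fry. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.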

Results

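Transcript levels were measured in whole skin of p63 null and wild-type mouse embryos at E18.5, late in gestation, with 2 embryos per genotype on each of 2 array types, the A chip and the B chip. The comparison asks which transcripts of late embryonic skin differ when p63, a transcription factor of stratified epithelia encoded by Trp63, is missing. Log2 values of the tested probe sets correlated between the 2 wild-type arrays at r = 0.984 on the A chip and 0.966 on the B chip. Between the 2 null arrays they correlated at 0.980 and 0.950. These correlations run across probe sets, which are not independent replicates. Between genotypes the correlations were lower, from 0.847 to 0.865 on the A chip and from 0.769 to 0.787 on the B chip. The ratio of 3' to 5' probe set signal of beta-actin, a measure of RNA integrity and labelling, was 1.63 and 1.69 in the wild-type arrays of the A chip and 1.27 in both null arrays. On the B chip it was 1.51 and 1.98 in wild type and 1.36 and 1.33 in the null. The same ratio for Gapdh on the A chip was 1.47 and 2.46 in wild type and 1.25 and 1.45 in the null. The null array numbered 2 on each chip stood apart in its hybridisation spikes, control transcripts added to each sample. The 3' probe set of the CreX spike read 6420 in it against 3334 to 3837 in the other A-chip arrays, and 32512 against 16966 to 18942 on the B chip. Without null replicate 2, 1428 probe sets were higher and 1574 lower on the A chip, and 1061 and 1210 on the B chip.

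Trp63 itself had a signal of 379.3 and 347.1 in the wild-type embryos and 61.9 and 46.6 in the null embryos on the A chip, a log2 fold change of -2.49 (SE 0.18, adjusted p = 1.13e-05). Where this probe set lies relative to the mutation is not given in the sources used here, so the value checks the genotype labels only if the probes lie in, or depend on, the altered part. The largest falls in null skin included genes of the cornified layer. Loricrin (Lor), the main protein of the cornified envelope, fell from 6590 ± 180 (SD, n = 2) to 143 ± 26.7, a log2 fold change of -5.42 (SE 0.14, adjusted p = 2.63e-08). The serpin Serpina12 fell from 1134 ± 9.48 to 12.4 ± 4.45 (log2 fold change -5.52, SE 0.18, adjusted p = 7.24e-08). The log2 fold changes of Crct1, Ggct, Hal (histidine ammonia-lyase, which makes urocanic acid in the cornified layer), Fgfbp1, Rnf227 and Il1f5 (an antagonist of the interleukin-36 receptor) were -5.20, -5.06, -5.04, -4.76, -4.63 and -4.55, with adjusted p-values of at most 3.00e-07.

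The largest rises were those of an acute phase gene and a brown fat gene. Saa3, a serum amyloid A protein of the acute phase, rose from 29.2 ± 5.52 (SD, n = 2) to 2481 ± 307 (log2 fold change 5.89, SE 0.16, adjusted p = 2.64e-08). Ucp1, the uncoupling protein of brown fat, rose from 32.8 ± 1.48 to 1941 ± 116 (5.42, SE 0.14, adjusted p = 2.63e-08). The chemokines Ccl8 and Cxcl5 rose by 4.89 and 3.40 on the log2 scale, the calcium-binding proteins S100a8 and S100a9, abundant in neutrophils and in stressed keratinocytes, by 4.17 and 3.90, the lipid droplet protein Cidea by 3.77 and the macrophage elastase Mmp12 by 3.65, with adjusted p-values of at most 3.84e-06. In all, 1646 of the 7453 tested probe sets of the A chip were higher and 1653 lower in the null by limma, together 44.3%, and 492 and 511 of these differed at least 2-fold. With each gene read by its highest-mean probe set, 1297 of 5779 genes were higher and 1316 lower. Both null arrays lay on one side of both wild-type arrays for 73.9% of tested probe sets, where chance gives 33.3%. Without wild-type replicate 2 the counts were 1075 higher and 1052 lower.

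**Figure D1:**
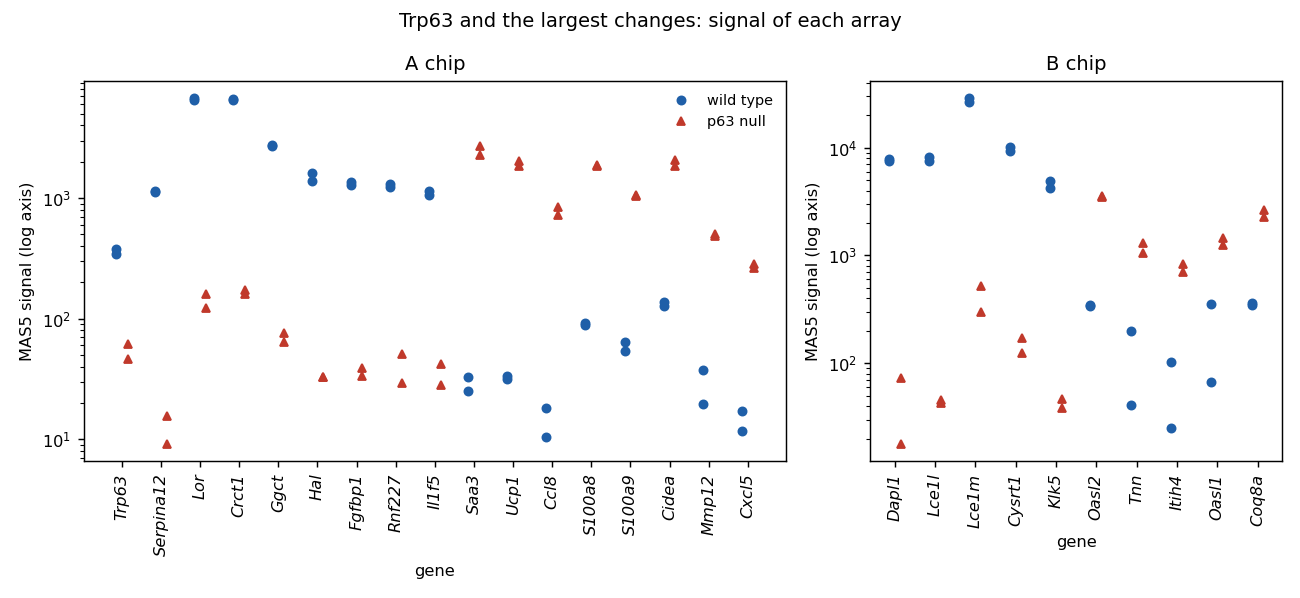
MAS5 signal (log axis) of Trp63 and of the genes with the largest falls and rises in each array of the A chip (left) and the B chip (right), with a circle per wild-type embryo and a triangle per null embryo. The triangles of a gene lie all below its circles, as for Lor (mean 6590 in wild type and 143 in the null), or all above them, as for Saa3 (29.2 and 2481).

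The keratinocyte lists fell on the A chip. Of 15 basal keratinocyte genes 13 fell and 0 rose (14 fell when adjusted over the list alone), with a median log2 fold change of -2.49 and a camera adjusted p of 1.77e-09 (adjusted p = 0.136 with an estimated correlation). Perp, a desmosomal membrane protein, fell from 6287 ± 403 (SD, n = 2) to 342 ± 119, and Lgals7, Sfn and the hemidesmosomal collagen Col17a1 fell, with log2 fold changes of -3.52, -3.17 and -2.96. Krt5 and Krt14, the classical basal keratins, could not be compared, because their probe sets read at most 15.9 in all arrays and stayed below the level for testing. Of 18 suprabasal genes 14 fell and 3 rose (the same numbers adjusted over the list alone), with a median of -1.52 and a camera adjusted p of 2.77e-07 (adjusted p = 0.136 with an estimated correlation). Serpinb5, Dsc1, Ly6g6c and Cdsn, the protein of corneodesmosomes, fell, with log2 fold changes of -4.51, -4.48, -4.27 and -3.71. The suprabasal keratins Krt1 and Krt10, chosen after their values were seen, fell, with log2 fold changes of -3.14 and -1.71. The 3 members that rose, also named after their values were seen, were Krt6a (1.63, adjusted p = 6.86e-06) and Krt16 (1.05, adjusted p = 0.00202), keratins of wounded and hyperproliferative epidermis and of the hair follicle, and the receptor Notch3 (0.92, adjusted p = 0.000404), which blood vessel walls also express.

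The cornified envelope list was divided. Of its 18 tested genes 11 fell and 3 rose (11 and 5 adjusted over the list alone), with a median of -1.23 and a camera adjusted p of 0.00208 (adjusted p = 0.292 with an estimated correlation, and 0.128 with the filter at the 60th percentile). Involucrin (Ivl) fell from 653 ± 9.48 to 16.1 ± 5.23 and filaggrin (Flg) from 5936 ± 183 to 266 ± 22.2. S100a8, S100a9 and the small proline-rich protein Sprr2b rose, the last by 0.55 (adjusted p = 0.00310), named after its value was seen. All 8 epidermal lipid barrier genes past the threshold, of 12 tested, fell (9 adjusted over the list alone). Their list had a median of -0.98 and a camera adjusted p of 2.90e-05 (adjusted p = 0.129 with an estimated correlation). Alox12b, the lipoxygenase of the lipid envelope, Sult2b1, Elovl6 and Degs2 fell, with log2 fold changes of -4.31, -3.18, -1.42 and -1.27.

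Desmosome and adherens junction genes fell in 10 of 12 cases and rose in 0 (the same numbers adjusted over the list alone), with a median of -2.97, a camera adjusted p of 1.10e-07 and an adjusted p = 0.118 with an estimated correlation. They included Dsc1, Perp, Pkp3 (-4.10) and Cdsn. Of 19 hair follicle genes 11 fell and 0 rose, also when adjusted over the list alone, with a median of -1.05 and a camera adjusted p of 1.09e-05 (adjusted p = 0.136 with an estimated correlation). Krt25, a keratin of the inner root sheath, the transcription factors Dlx3 and Gata3, and the hedgehog receptor Ptch1 fell, with log2 fold changes of -4.14, -3.65, -3.38 and -2.92. Simple epithelium genes included 4 that fell of 10 tested, and 0 that rose (the same numbers adjusted over the list alone). The median of the list was -0.26 with a camera adjusted p of 0.00920 (adjusted p = 0.154 with an estimated correlation, and 0.0993 without wild-type replicate 1). Spint1, Esrp1 and Cldn4 fell, with log2 fold changes of -3.92, -3.65 and -2.25, and the protease Prss8 fell by 0.63 (adjusted p = 0.0187). The call for Prss8 was lost without wild-type replicate 1 (adjusted p = 0.0907), without wild-type replicate 2 (0.0610) and without null replicate 2 (0.0626). Krt8, named after its value was seen, had a log2 fold change of -0.17 (adjusted p = 0.519).

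The proposed p63 targets, 15 of whose 46 members are also in other lists, fell in 15 of 25 tested cases and rose in 2 (16 and 2 adjusted over the list alone). Their median was -1.11 with a camera adjusted p of 1.05e-06 (adjusted p = 0.136 with an estimated correlation). Alox12b, Perp, Dlx3 and the transcription factor Tfap2c (-3.52) led the falls. The 2 that rose, named after their values were seen, were the growth factor binding protein Igfbp3 (0.47, adjusted p = 0.0115) and the cell cycle inhibitor Cdkn1c (0.67, adjusted p = 0.00808). Both calls were lost without wild-type replicate 1 (adjusted p = 0.0725 and 0.121), and that of Igfbp3 also without wild-type replicate 2 (adjusted p = 0.0672). Camera with an estimated correlation also missed the shift put into the simulated A chip. The simulated genes varied independently, so that run cannot decide between the preset and the estimated correlation here. The beta-actin 3'/5' ratio, 1.63 and 1.69 in wild type and 1.27 in both null arrays, moved with genotype beside these falls.

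Markers of muscle, adipocytes, leukocytes, endothelium and fibroblasts moved the other way. Of 34 skeletal muscle genes 33 rose and 0 fell (33 and 1 adjusted over the list alone), with a median log2 fold change of 1.27 and a camera adjusted p of 2.44e-14 (adjusted p = 0.118 with an estimated correlation). Atp2a1, the calcium pump of the sarcoplasmic reticulum, rose from 923 ± 8.77 (SD, n = 2) to 3238 ± 334, and the myosins Myh1 and Myh3 and the troponin Tnnt1 rose by 1.82, 1.79 and 1.77. Of 18 adipocyte genes 15 rose and 0 fell, also when adjusted over the list alone, with a median of 0.97 and a camera adjusted p of 1.77e-09 (adjusted p = 0.118 with an estimated correlation). After Ucp1 and Cidea, the largest rises in this list were those of the lipid droplet protein Plin4 (2.20) and of Gpd1 (2.16). Leukocyte genes rose in 17 of 23 cases and fell in 0 (18 and 0 adjusted over the list alone), with a median of 0.97 and a camera adjusted p of 2.77e-07 (adjusted p = 0.118 with an estimated correlation). The complement genes C1qa and C1qc, the protease Ctss and the lysozyme Lyz2, products of macrophages, rose by 2.09, 1.64, 1.98 and 1.59.

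Endothelial genes rose in 14 of 17 cases and fell in 0, also when adjusted over the list alone, with a median of 0.58 and a camera adjusted p of 6.31e-05 (adjusted p = 0.154 with an estimated correlation). Tie1, Eng, Flt1 and Cdh5 rose by 1.03, 0.96, 0.94 and 0.90. Flt1 on the B chip had a value of -0.03 (adjusted p = 0.957). The dermal fibroblast and matrix list had a smaller median, 0.32, with 15 of 33 genes higher and 1 lower (the same numbers adjusted over the list alone) and a camera adjusted p of 0.000586 (adjusted p = 0.154 with an estimated correlation). Tenascin C (Tnc), a matrix protein of wounds, rose from 198 ± 26.1 (SD, n = 2) to 1628 ± 139, a log2 fold change of 2.97, while Pdgfrb and Tgfbi rose by 0.94 and 0.82 and Ogn, the proteoglycan osteoglycin, fell by 0.83. The lower beta-actin 3'/5' ratios of the null arrays (1.27 in both) went with these rises too.

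Erythroid genes were not distinguishable as a list, with a median of 0.23 over 11 genes and a camera adjusted p of 0.181. Slc4a1, Hbb-b2 and Car2 rose by 0.59, 0.43 and 0.41, and 0 of them passed when adjusted over the list alone. All 3 calls were lost without wild-type replicate 1 (adjusted p = 0.0968, 0.177 and 0.146) and without wild-type replicate 2 (0.0517, 0.253 and 0.111). Those of Slc4a1 and Car2 were lost without null replicate 1 (0.0549 and 0.0676) and that of Car2 without null replicate 2 (0.0810). Median centring ended those of Hbb-b2 (0.0606) and Car2 (0.0519). That of Hbb-b2 was also lost with no filter (0.0847), no variance trend (0.0649) and the replicate block (0.0539). In the list of Schwann cells, neurons and melanocytes 3 of 13 genes fell and 1 rose (3 and 0 adjusted over the list alone), with a median of -0.04 and a camera adjusted p of 0.481. The neuregulin receptor Erbb3 fell by 1.09, and the melanocyte genes Dct (-0.90) and Pmel (-0.74) fell too. Pmp22 rose by 0.36 (adjusted p = 0.0450), a call lost without wild-type replicate 1 (adjusted p = 0.238), wild-type replicate 2 (0.106) or null replicate 1 (0.137), and with median centring (0.0673), no filter (0.0856) or no variance trend (0.103). None of the 4 cartilage and bone genes tested passed in limma, the 2 with the highest signal being Col9a2 (0.28, adjusted p = 0.230) and Col9a1 (-0.05, adjusted p = 0.889), and 0 passed when adjusted over the list alone. Xist, the 1 sex-linked gene tested, had a log2 fold change of 0.25 (adjusted p = 0.392), and passed without null replicate 1 (0.63, adjusted p = 0.00681).

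Cell cycle genes fell in 23 of 31 cases and rose in 0 on the A chip, also when adjusted over the list alone. The list had a median of -0.78 and a camera adjusted p of 3.51e-07 (adjusted p = 0.129 with an estimated correlation). Beside this fall, the basal keratinocyte list had a median of -2.49 and the beta-actin 3'/5' ratio was 1.63 and 1.69 in wild type and 1.27 in both null arrays. The DNA primase Prim1, the mitotic checkpoint kinase Bub1, the spindle motor Kif11 and the microtubule regulator Stmn1 fell, with log2 fold changes of -1.95, -1.59, -1.40 and -1.38. Immediate early and stress genes went both ways, with 5 higher and 8 lower of 27 (the same numbers adjusted over the list alone), a median of -0.25 and a camera adjusted p of 0.181. The inducible heat shock genes Hspa1b and Hspa1a, whose probe sets can bind both transcripts, fell from 1185 ± 21.4 (SD, n = 2) to 105 ± 4.95 and from 563 ± 43.6 to 82.8 ± 50.4. Ddit4 and the co-chaperone Dnajb1 fell, with log2 fold changes of -1.69 and -1.14.

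**Figure D2:**
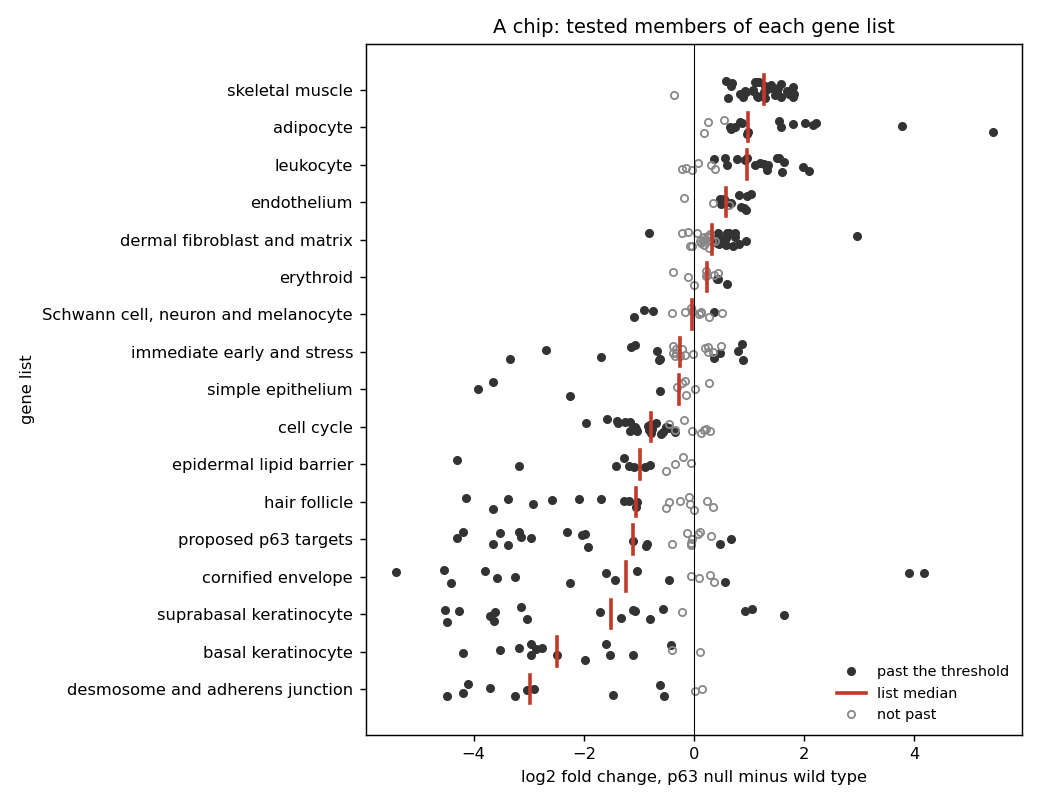
Log2 fold change, null minus wild type, of the tested members of the 17 gene lists with at least 5 tested genes on the A chip, with a filled point per gene past the threshold, an open point per other gene and a vertical line at each list's median. The medians run from -2.97 for the desmosome and adherens junction list to 1.27 for the skeletal muscle list.

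The B chip, which carries different probe sets, had larger falls than rises among its leading genes. Dapl1 fell from 7682 ± 251 (SD, n = 2) to 45.0 ± 38.4 (log2 fold change -6.34, SE 0.25, adjusted p = 6.22e-06). The late cornified envelope genes Lce1l and Lce1m, whose probe sets can bind other family members, fell, with log2 fold changes of -6.33 and -5.93, and so did Cysrt1 (-5.60) and Klk5, a protease of corneocyte shedding (-5.57). The interferon-induced gene Oasl2 rose from 341 ± 3.04 to 3544 ± 53.5 (3.19, SE 0.13, adjusted p = 6.39e-06). The matrix protein Tnn rose by 2.99, Itih4 by 2.88, Oasl1 by 2.67 and Coq8a by 2.62, with adjusted p-values of at most 0.00687. The wild-type arrays differed for Tnn (40.8 and 197.9) and Oasl1 (350.7 and 67.4), so that Tnn had a log2 fold change of 2.29 without wild-type replicate 1 and 3.67 without wild-type replicate 2, and Oasl1 one of 3.54 and 1.80. Of 7446 tested probe sets 1083 were higher and 1106 lower by limma, together 29.4%, of which 320 and 479 differed at least 2-fold. With each gene read by its highest-mean probe set, 859 of 5345 genes were higher and 855 lower. Groups did not overlap for 67.7% of probe sets, where chance gives 33.3%. The counts were 603 higher and 572 lower without wild-type replicate 1, and 575 and 544 without wild-type replicate 2.

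Epidermal lists fell on the B chip as well. Of 6 basal keratinocyte genes 5 fell and 0 rose, with a median of -2.72 and a camera adjusted p of 9.79e-05 (adjusted p = 0.104 with an estimated correlation). They included Krt15 (-3.71), Trim29 (-3.10), Dst (-3.01) and Lad1 (-2.44). Of 9 suprabasal genes 8 fell, among them Sbsn (-4.31), Dsc1 (-4.08), Lypd3 (-2.49) and Ly6g6c (-2.45), and 1 rose, for a median of -2.40 and a camera adjusted p of 1.02e-06 (adjusted p = 0.104 with an estimated correlation). The 1 that rose was again Krt6a (0.83, adjusted p = 0.0103), named after its value was seen, and its call was lost without wild-type replicate 2 (adjusted p = 0.0732). Of 9 cornified envelope genes 8 fell and 0 rose, with a median of -3.33 and a camera adjusted p of 6.46e-10 (adjusted p = 0.104 with an estimated correlation). Klk5, Klk7 (-4.18), Lce1f (-4.14) and Lce1a1 (-3.94) led these. Of 7 desmosome and adherens junction genes 5 fell and 0 rose (median -2.40, camera adjusted p = 9.79e-05, adjusted p = 0.104 with an estimated correlation), among them Dsc3 (-4.24), Evpl (-2.57) and Dsg1a (-2.40). All 6 hair follicle genes tested fell (median -1.82, camera adjusted p = 2.21e-05, adjusted p = 0.104 with an estimated correlation), including Krt73 (-2.23), Gata3 (-2.19), Ptch1 (-2.16) and Sostdc1 (-1.47). The counts in these 5 lists were the same when adjusted over the list alone. The beta-actin 3'/5' ratios of this chip, 1.51 and 1.98 in wild type and 1.36 and 1.33 in the null, moved with genotype as well.

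Of 12 proposed p63 targets on the B chip 7 fell and 0 rose, also when adjusted over the list alone, with a median of -0.54 and a camera adjusted p of 0.000278 (adjusted p = 0.241 with an estimated correlation). Zfp750, a regulator of terminal differentiation, and the kinase Ripk4 fell, with log2 fold changes of -2.78 and -2.59, and Gata3 and Satb1 with -2.19 and -1.19. Of 6 epidermal lipid barrier genes only Lipm (-5.04, adjusted p = 5.81e-06) passed, also adjusted over the list alone, and the list did not (median -0.36, camera adjusted p = 0.0540). That list did pass with quantile normalization (adjusted p = 0.0489), median centring (0.0458), no filter (0.0184), the replicate block (0.0270) and fry (0.00131). Its median was -0.39 without wild-type replicate 1, -0.20 without wild-type replicate 2 and -0.37 without null replicate 2. Endothelial genes rose in 6 of 7 cases and fell in 0, also when adjusted over the list alone, with a median of 0.77 and a camera adjusted p of 0.00273 (adjusted p = 0.173 with an estimated correlation). Plvap and Lyve1 rose by 1.39 and 0.85. Ptprb rose by 0.78 (adjusted p = 0.0546 without wild-type replicate 2). Eng rose by 0.77 (adjusted p = 0.0979 without wild-type replicate 1 and 0.0754 without wild-type replicate 2).

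The remaining lists had fewer than 5 tested genes on the B chip and got no list test. Of 4 skeletal muscle genes Ttn, Mybpc1 and Car3 rose by 1.76, 1.52 and 1.14 (4 rose when adjusted over the list alone). Of 2 adipocyte genes Agpat2 rose by 2.01, and of 4 genes of Schwann cells, neurons and melanocytes Ednrb rose by 0.90. St14 and Ap1m2 fell, with log2 fold changes of -3.50 and -1.70 among 3 simple epithelium genes (the remaining 1, Spint1, which fell on the A chip, had a value of 0.86 and was higher only when adjusted over the list alone). Of 3 cell cycle genes Bub1b fell by 1.02 and Foxm1 fell by 0.57, the latter with an adjusted p of 0.0492 and of 0.114 without wild-type replicate 1, 0.309 without wild-type replicate 2 and 0.0749 without null replicate 1. The call for Foxm1 was also lost with quantile normalization (adjusted p = 0.0575), median centring (0.0561), no offset (0.0512) and a floor (0.0508). No filter (0.0878), no variance trend (0.0506) and the replicate block (0.0518) ended it too. On the A chip Foxm1 had a value of 0.13 (adjusted p = 0.550). Of 3 erythroid genes Sptb and Bpgm rose by 0.58 and 0.53, calls lost without wild-type replicate 1 (adjusted p = 0.223 and 0.114) and without wild-type replicate 2 (0.0639 and 0.106). Sptb was also lost without null replicate 2 (0.0665), with no filter (0.0595) and with no variance trend (0.0563), and Bpgm with no variance trend (0.0515). Bpgm had a value of -0.12 (adjusted p = 0.586) on the A chip. Mt1, 1 of 2 immediate early and stress genes, rose by 0.76 (adjusted p = 0.0706 without wild-type replicate 2). Neither Aspn (0.21, adjusted p = 0.265) nor Col14a1 (0.30, adjusted p = 0.132), the brightest of 3 fibroblast genes, passed. Apart from muscle and simple epithelium, these counts did not differ when adjusted over the list alone. No leukocyte, cartilage and bone or sex-linked gene was tested on this chip.

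Genes with a tested probe set on both chips allowed a repeated measurement with other probes. Over 1063 such genes the log2 fold changes of the chips correlated across genes at a Pearson r of 0.646 and a Spearman rho of 0.568, and 68.6% had the same sign. Genes are not independent replicates, and no source says that the chips were hybridised with RNA from separate embryos. Of the 443 genes past the threshold on the A chip, 81.7% had the same sign on the B chip. Both chips called 206 genes, where independent lists would share 138, and 198 of these had the same direction, 110 lower and 88 higher, where independent lists would share 40.2 and 28.8. Dsc1 had a log2 fold change of -4.48 on the A chip and -4.08 on the B chip. Spint1, which fell by 3.92 on the A chip, had a value of 0.86 on the B chip that did not pass, and was chosen after its values were seen. The 8 genes called in opposite directions, named after their values were seen, were Zwint, Cul1, Aopep, Cnot2, Atp11a, Nudt19, Ogt and Edem2, with log2 fold changes between -0.88 and 1.33. Within a chip, 12 of 860 genes with several tested probe sets had calls in both directions on the A chip and 7 of 1164 on the B chip. Of the 550 such genes with any call on the A chip 333 had some but not all of their probe sets called, and 381 of 530 on the B chip.

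**Figure D3:**
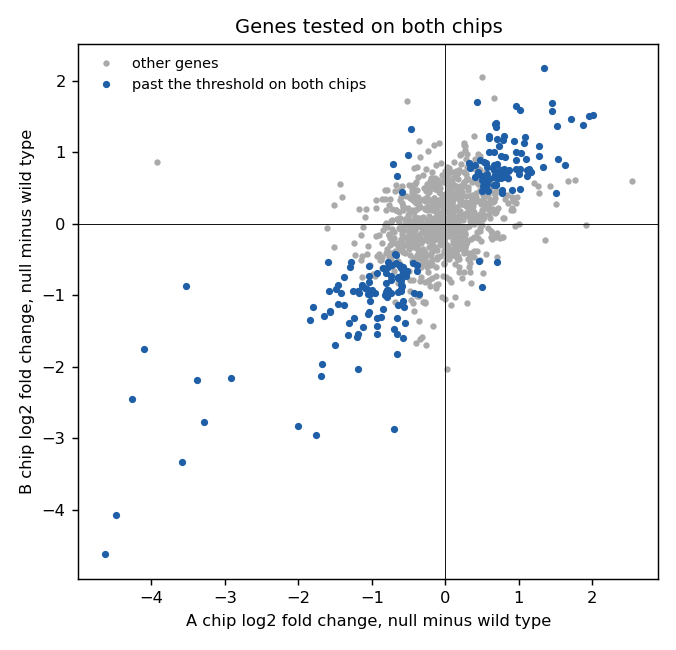
Log2 fold change, null minus wild type, on the A chip against that on the B chip, with a point per gene tested on both and darker points for genes past the threshold on both. The 1063 genes have a Pearson r of 0.646 across genes, and 8 genes called on both chips lie in opposite quadrants.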

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

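Several mouse pyruvate carboxylase control probe sets, which took no part in the tests, had signals in both null arrays above those of both wild-type arrays. They were noticed only when the control probe sets were looked through. Those given here passed a cutoff of 2-fold with null signals above the chip's median. On the A chip the lower null array over the higher wild-type array was 3.13 for the 3' probe set, 2.34 for the 5' probe set and 2.16 and 3.05 for the probe sets in between. On the B chip it was 3.24 for the 3' probe set, 2.09 for the 5' probe set and 2.46 for 1 of the probe sets in between. The 3' probe set read 476.4 and 480.8 in wild type and 1602 and 1504 in the null on the A chip, and 2048 and 2087 against 6770 and 7206 on the B chip. Pcx, the tested gene for the same enzyme, named after its value was seen, rose by 1.84 on the log2 scale in limma (SE 0.21, adjusted p = 0.000163).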

How the results depend on the processing

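None of the settings in this part was added after the data were seen. Direction was checked only for results called in the main fit, for genes and lists alike. Of the comparisons of 197 gene results with their values under 16 alternatives, 2980 kept their side of the threshold, 98 lost the call (35 of them with the 2-fold threshold), 13 gained it and 0 calls reversed. For 25 lists the numbers were 441, 23, 10 and 0, and 21 of the 23 lost calls came from the estimated correlation. For 10 later lists, 138 comparisons moved the median by at most the median SE of its genes and 12 by more, 4 of these with the 40th percentile offset and 2 without wild-type replicate 1. With the estimated correlation camera called 0 lists on either chip, although 6 of 17 lists on the A chip and 3 of 8 on the B chip had an unadjusted p under 0.05, fry called 16 and 8, and the preset correlation called 14 and 7. Higher and lower calls numbered 492 and 511 on the A chip and 320 and 479 on the B chip with a 2-fold threshold, which by construction removes smaller changes. The correlation between chips was 0.533 without a filter and 0.726 with the filter at the 60th percentile, and its cause was not tested. With 1 array left out, where the lone array is assumed to vary like the other genotype, higher calls ranged from 1075 to 1579 and lower calls from 1052 to 1797 on the A chip, from 575 to 1244 and from 544 to 1354 on the B chip, called lists from 13 to 14 and from 7 to 8, and the correlation between chips from 0.609 to 0.651. Deviations of arrays with the same number correlated across probe sets at 0.0389 on the A chip and -0.0465 on the B chip. The Gapdh 3'/5' ratio was nonetheless higher in array 2 than in array 1 in both genotypes on both chips. On the B chip it was 1.55 and 2.66 in wild type and 1.26 and 1.51 in the null. Structure shared by the numbers is therefore not excluded. The replicate block gave 1674 higher and 1694 lower calls on the A chip and 1229 and 1182 on the B chip. It called 14 and 8 lists, the added one being the epidermal lipid barrier (adjusted p = 0.0270). The block ended the calls of Hbb-b2 (adjusted p = 0.0539), Foxm1 (0.0518) and, named after its value was seen, Dcn on the A chip (0.0728). Low signals limit the folds of genes near the offset, and no detection calls were at hand to place a background.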

Other observations

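The lists of interferon-stimulated, acute phase, heat shock, brown fat, general adipocyte, liver and neutrophil granule genes, the comparisons with random lists and the permutation tests between lists were chosen only after the leading genes had been seen, so their counts describe these arrays and are not independent evidence. The genes named from these lists were chosen in the same way, apart from those the report names by its rule. Interferon-stimulated genes were higher in null skin in nearly all cases tested. On the A chip 23 of 24 rose in limma and 0 fell, with a median log2 fold change of 1.75 that lay above 100% of 10000 random lists matched on level. Irf7, Usp18, Isg15 and Gbp3 were among those that rose, and Ifit2 (0.55, adjusted p = 0.0513) was the 1 that did not pass. All 12 tested on the B chip rose, with a median of 1.70, including Bst2, Ddx58, Ddx60 and Parp9. Acute phase and related genes rose in 11 of 13 cases on the A chip and fell in 1, with a median of 1.58 (percentile 100). Cp, Serpina3n, Lrg1, Serping1 and Hp, which encode ceruloplasmin, a serpin, a plasma glycoprotein, the C1 inhibitor and haptoglobin, rose, and Orm1 fell by 0.62 (adjusted p = 0.00402). Beside the rises of both lists, the leukocyte list had a median of 0.97 on the A chip. The beta-actin 3'/5' ratio there was 1.63 and 1.69 in wild type and 1.27 in both null arrays.

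Heat shock genes went both ways. Of 17 tested on the A chip 6 fell and 3 rose, with a median of -0.22 (percentile 6.90). Hsp90aa1 fell by 0.80 (adjusted p = 0.000979) beside Hspa1b, Hspa1a and Dnajb1, while Hspa8, Hspd1 and Hspe1, expressed without stress, did not pass (adjusted p = 0.450, 0.918 and 0.524). Cryab, a small heat shock protein that muscle expresses at high level, rose.

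The muscle, adipocyte, leukocyte, endothelial and fibroblast lists rose in the null, with A-chip medians of 1.27, 0.97, 0.97, 0.58 and 0.32. Of these only muscle and fibroblast were compared by a test. On the A chip the erythroid list and that of Schwann cells, neurons and melanocytes did not pass in camera. A fall in the share of epidermal RNA raises all other types alike. The median of the muscle list rose by 0.948 more than that of the fibroblast list, and by 0.76 to 1.06 more under 15 alternatives. Permutation over 34 and 33 genes gave p = 1e-05, the smallest that 100000 permutations can give. It treats the genes as independent and does not measure variation between embryos. The lists compared had the highest and the lowest of these medians, so some difference was given in advance. The size of the gap in these embryos argues against dilution alone. More muscle carried in the null dissections stays open, since 97.1% of the tested muscle genes were higher. A larger muscle share of the null skin itself predicts the same, and the arrays cannot tell these apart.

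Genes of brown fat were higher in the null, with 12 of 14 tested on the A chip higher, a median of 1.42, and 6 of 8 on the B chip. The median of the 14 was 0.683 above that of a general adipocyte list (permutation over 14 and 11 genes, p = 0.0375, and from 0.0283 to 0.0760 under 15 alternatives with 10000 permutations each, with 0.0561 without null replicate 1), but 8 of them are also expressed by skeletal muscle, whose list rose, and the test was therefore repeated, after that result was seen, without those 8. The median of the 6 others was 0.859 above that of the adipocyte list (permutation over 6 and 11 genes, p = 0.0530, and from 0.0150 to 0.672 under 15 alternatives, under 0.05 in 3 of them, without wild-type replicate 2 (0.0260), without null replicate 2 (0.0265) and with the filter at the 60th percentile), so a larger amount of the fat already in wild-type skin is not excluded, with Ucp1 and Cidea far up and Dio2 and Zic1 not past the threshold. Brown fat carried in the null dissections may add to the pattern, as the 5 members tested on the A chip whose values had not been looked up had a median above 99.98% of random matched lists and 4 of 5 such members on the B chip rose (median 0.85), but all 5 on the A chip and 3 of the 5 on the B chip are expressed by muscle too, which keeps it open. A difference of the fat in null skin itself was not tested apart from these.

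The rise of acute phase and innate immune genes has several candidate sources besides the skin. Blood as read by its red cells is argued against in these embryos by the small rise of the erythroid list (median 0.23), written before the data were examined. The median of the erythroid list minus that of the acute phase list was -1.35 (permutation over 11 and 13 genes, p = 0.00458). A gap was likely in advance, because the acute phase list was chosen after its leading genes were seen. The permutation also treats the genes as independent and does not measure variation between embryos. Under 15 alternatives the difference lay between -2.24 and -0.92, with p at most 0.0206. The smallest gap, -0.92 with the 40th percentile offset, missed the cutoff set after the data were seen. The erythroid list does not speak for blood leukocytes, which were not tested as a source. Liver could not be decided. Its list without Alb had a median of 0.173 on the A chip from the 1 gene tested there, Rbp4, and Trf on the B chip had 0.04 (limma adjusted p = 0.890). Alb rose from 47.5 and 41.9 to 268.8 and 285, while the signals of Afp, Apoa1 and Ttr were at most 42. Of 22 liver probe sets below the level for testing 3 had both null arrays at least 2-fold above both wild-type arrays, 8 were above by less, 8 overlapped and 3 were lower. Those at least 2-fold above were Serpina1b (5.9 and 6.9 to 65.1 and 60.6), Fga (12.3 and 10.3 to 42.1 and 44.6) and 1 Apoa2 probe set (6.5 and 6 to 38.6 and 30). The other Apoa2 probe set was lower in the null. Neutrophils are open as well, with a granule gene median at percentile 93.67 over 5 tested genes, of which 3 are in the leukocyte list and Camp (-0.14) and Elane (0.31) did not pass, and at percentiles from 89.11 to 100 under 15 alternatives, over 95 only with no filter (99.97), without wild-type replicate 1 (99.55) and without wild-type replicate 2 (100), where 16, 7 and 8 genes were tested. Lyz2 (1.59), Lcn2 (0.78) and Csf3r (0.48) passed, the calls of Lcn2 and Csf3r being lost under some alternatives. Lcn2 was read there by its probe set with the highest mean signal. Its other probe set, also tested, went from 12.2 and 12.5 in wild type to 246 and 226.3 in the null. Of 16 neutrophil probe sets below the level for testing 5 had both null arrays at least 2-fold above both wild-type arrays, 4 were above by less, 6 overlapped and 1 was lower. The 5 were Ltf (7.7 and 6.7 to 85.9 and 71), Mmp8 (9.9 and 5.4 to 103.7 and 113.7), Ngp (13.8 and 11.7 to 101.9 and 91.3) and the Mmp9 probe sets. The brighter Mmp9 probe set went from 8.6 and 3 to 127 and 136.8. An inflammatory response of the null skin itself was not tested apart from these.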
